A study of Mus musculus with 3 samples.

How the data were processed

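Gene expression was measured by RNA sequencing in macrophages sorted from mouse lung at 0, 4 and 24 h, with 1 library per time point. Per the labels' protocols, lungs were minced and digested for 50 minutes at 37 degrees, and cells were sorted on GFP, absence of Ly6g and presence of CD64. The column headings also carry the name of the surface marker CD11b, which the sorting text does not mention. Samples were grouped by the time point in the labels.

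The data used were 3 tables of the authors, each comparing 2 libraries. Per the submitters' processing notes the tools included DESeq2, with no version, and the genome build was mm10. The aligner, the read counter and the annotation are not given in the sources used here, so the handling of reads shared between paralogs, pseudogenes and overlapping genes is unknown. The deposited signal values are read counts per gene divided by a size factor fitted within each table's pair of libraries. Every value was a whole multiple of its column's smallest step, within a tolerance of 0.001 reads, so whole reads were recovered for 100% of values. The tables list genes whose mean over the pair is above 10. The deposited log2 fold changes are those of the later library over the earlier and are shrunken toward 0, per the file headers and the values. A deposited log2 value of 1 corresponded to a median plain ratio of 2.50-fold at 4 h against 0 h, 2.93-fold at 24 h against 0 h and 2.58-fold at 24 h against 4 h, so counts past the threshold are not comparable between tables. The deposited p-values are not adjusted, and the authors' mark of significance is set where p is below 0.05 and nowhere else.

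The first column of the table comparing 0 h and 24 h is headed as 4 h. Its recovered reads equal those of the 0 h library in 12310 of 12310 shared genes and those of the 4 h library in 0.471% of them. This 1 column was given to no sample and used only for that check. Levels at 0 h come from the table of 4 h against 0 h. The deposited fold changes of 24 h against 0 h were read as their table is named. The same table repeats 20 genes, and the repeats were dropped, leaving 12618.

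The planned rule counted genes by an adjusted p-value. Benjamini-Hochberg adjustment of the deposited p-values left no gene below 0.05 in any table, with lowest adjusted values of 0.592 at 4 h against 0 h, 0.99993 at 24 h against 0 h and 0.998 at 24 h against 4 h, all resting on DESeq2 fits to 1 library per time point. The planned fallback was therefore used, a count of genes with a deposited log2 fold change of at least 1 in size, with no p-value. No count model was fitted to the recovered reads, since 1 library per time point leaves no residual degrees of freedom. Terms such as higher and lower describe these libraries and not the conditions.

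For levels, recovered reads were divided by median-of-ratios size factors over genes with a value in all 3 libraries (1.07 at 0 h, 0.788 at 4 h and 1.22 at 24 h). Folds are ratios of these normalized counts. Their 95% intervals come from the exact binomial interval of Clopper and Pearson on the reads of both libraries and cover counting error only, since reads without molecular identifiers are not independent molecules. Log2 ratios across genes used a pseudocount of 1.

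Before the data were examined, 40 lists of pathway genes and cell type markers were fixed, with 756 genes, of which 703 matched a table by symbol, 14 by a synonym at the same location and 39 not at all. For each list the median deposited log2 fold change was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a median below the 2.5 or above the 97.5 percentile is described as outside the central range. Members passing 0.05 after adjustment of the authors' p-values over the list alone were counted as well.

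Named genes followed a rule fixed at the same time. In each comparison it takes the 6 genes with the highest and the 6 with the lowest deposited log2 fold change among those with a mean at or above the 75th percentile, leaving out predicted genes. From each list described it takes the 2 members furthest up and the 2 furthest down past the threshold, or the most abundant member when none is past it, and it adds the sorting and lineage genes and the neutrophil genes S100a8 and S100a9. The rule asked for genes past an adjusted p-value, which was left out because none passed. Some genes that the rule picks are not reported here. Other genes named outside it were chosen after their values were seen: Ccr2, Krt79, Pparg and Ccl6 at 4 h, the genes with wide ratios at 24 h against 0 h, the sex-linked genes, Lyz1 and Mki67.

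The steps were tested on simulated counts with 200 genes changed by a log2 fold of 2 or 3. At 24 h against 0 h, 99.0% of the genes changed by 2 and 100% of those changed by 3 were recovered at a log2 ratio of 1, and all were in the other comparisons. These are plain ratios with counting error only, so they give no recovery rate for the threshold on the shrunken deposited fold changes. Counting error alone put 54 of 12312 unchanged genes past a plain log2 ratio of 1 at 4 h against 0 h. That was so for 79 of 12281 at 24 h against 0 h and 91 of 12484 at 24 h against 4 h. Counting intervals held the true fold in 94.2%, 94.8% and 94.6% of 500 genes. Alternatives covered p-value thresholds, filters on the mean, recentring on the median gene or on ribosomal proteins, plain ratios with pseudocounts of 1 and 5, and, for the lists, unmatched random lists, no shared members and summed fold changes. Added after seeing the data were the authors' own calls, an adjusted p of 0.05, a mean of at least 100, omission of chromosomes X and Y, removal of length and GC trends, plain ratios of at least 8-fold and, for the lists, plain ratios and recentring on ribosomal proteins. The return of genes at 24 h was set beside 100 simulations of libraries with no effect that share the 4 h library. Their spread per library was set from the 24 h against 0 h ratios. Lengths and GC content were those of the GENCODE vM21 transcripts of each gene, as the median, with the longest used as well for neutrophil and monocyte genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Genes that the tables do not list, among them Ly6g and the mitochondrially encoded genes, were not analysed here.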

Results

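Bulk RNA sequencing was carried out on macrophages sorted from the lungs of LysM-GFP mice, a C57BL/6 strain in which myeloid cells carry a green fluorescent reporter driven from the lysozyme M locus. The animals were 6 to 8 weeks old and acute lung injury was set off with nebulized lipopolysaccharide (LPS), the bacterial cell wall component sensed by TLR4, from a solution of 1 mg/ml. Cells that were GFP-positive, negative for the neutrophil antigen Ly6g and positive for the macrophage Fc receptor CD64 were collected at 0, 4 and 24 h, with 1 library at each time. The comparisons ask how lung macrophages at 0 h differ from those of the acute and resolution phases. The treatment text is the same for every sample, so whether the 0 h mice were untreated or taken right after nebulization is not known, and values against 0 h are differences from that library and not from an established resting state. The whole reads behind the deposited values came to 24825976 at 0 h over 12512 genes, 20379236 at 4 h over 12715 genes and 25135476 at 24 h over 12849 genes. The most abundant transcript was Chi3l3 (Chil3), a chitinase-like protein of alveolar macrophages, with 2.59% of the reads at 0 h and again first at 24 h, and at 4 h it was Il1b, encoding interleukin-1 beta, with 1.07%. Levels below are normalized read counts on a scale common to the 3 libraries. Folds are plain ratios of those counts with a 95% counting interval, which covers counting error only, and since no time point had a replicate no fold has a replicate check. Counts of list members passing when adjusted over the list alone rest on the authors' p-values from fits to 1 library per time point, and describe those values without testing the list.

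Transcripts of the sorting genes were present at every time but their levels shifted at 4 h. Fcgr1, which encodes CD64, stood at 2479 normalized counts at 0 h, 7237 at 4 h and 2887 at 24 h, and Itgam, encoding the integrin CD11b, at 7235, 33421 and 7385. Ptprc, the leukocyte antigen CD45, stood at 23843, 73267 and 34676. Siglec5, the tables' name for Siglecf, a surface lectin of alveolar macrophages, went the other way, with 10997 at 0 h, 779 at 4 h and 6211 at 24 h. Itgax, encoding CD11c, stood at 46583, 15772 and 22539, and Mertk, a receptor for apoptotic cells, at 10552, 1673 and 3194. The pan-macrophage genes Csf1r (29976, 40025 and 29673) and Emr1 (Adgre1, encoding F4/80, at 11991, 11815 and 8680) passed the size threshold in no comparison. The same held for the pan-macrophage genes Cd68 (21286, 13168 and 17754) and Sfpi1 (Spi1, encoding PU.1, at 9991, 10510 and 11718). Cx3cr1, listed here among interstitial macrophage markers, did not pass the threshold either (3337, 6494 and 4391). Lyz2, the reporter's own locus, had only 43, 16 and 21 reads, while its near-identical neighbour Lyz1 had 20125, 19635 and 18641. The split of reads between these paralogs is uncertain, and the cause of the low Lyz2 counts was not tested. Transcripts tied to sex also separated the libraries: Xist, the RNA of the inactive X chromosome, had 13705 reads at 0 h, 4 at 4 h and 1 at 24 h, whereas the Y-linked gene Ddx3y had 4, 3994 and 2357 reads and Eif2s3y 2, 2133 and 2925.

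At 4 h against 0 h, transcripts of classical monocytes and of the interferon response were far higher and those of alveolar macrophages and of cell division far lower. Vcan, a matrix proteoglycan made by classical monocytes (chromosome 13, 89655309 to 89742512, mm10), went from 247 to 55128 normalized counts, 224-fold (198 to 253). F13a1, a coagulation factor subunit, was 50.4-fold higher (48.2 to 52.7). In the other direction Krt19, a keratin expressed by alveolar macrophages (chromosome 11, 100140810 to 100143699), was 130-fold lower (102 to 170) than its 10419 at 0 h, and Cidec, a lipid droplet protein, was 30.6-fold lower (25.9 to 36.3). By the authors' deposited log2 fold changes, 1109 of 12512 genes lay at or above 1 and 1128 at or below -1.

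Other genes picked by the fixed rule among abundant transcripts had similar sizes. Saa3, an acute phase serum amyloid, was 64.2-fold higher (51.7 to 80.8), Tarm1, a receptor of activated myeloid cells, 56.1-fold higher (44.1 to 72.4), and Ccl5, a chemokine for T cells and monocytes, 43.4-fold higher (36.9 to 51.4). X99384, which the tables list under that name, was 41.3-fold lower (35.1 to 48.9), Mfsd7c 39.9-fold lower (32.3 to 49.8) and Cd2, an adhesion molecule, 28.5-fold lower (24.6 to 33.2).

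**Figure D1:**
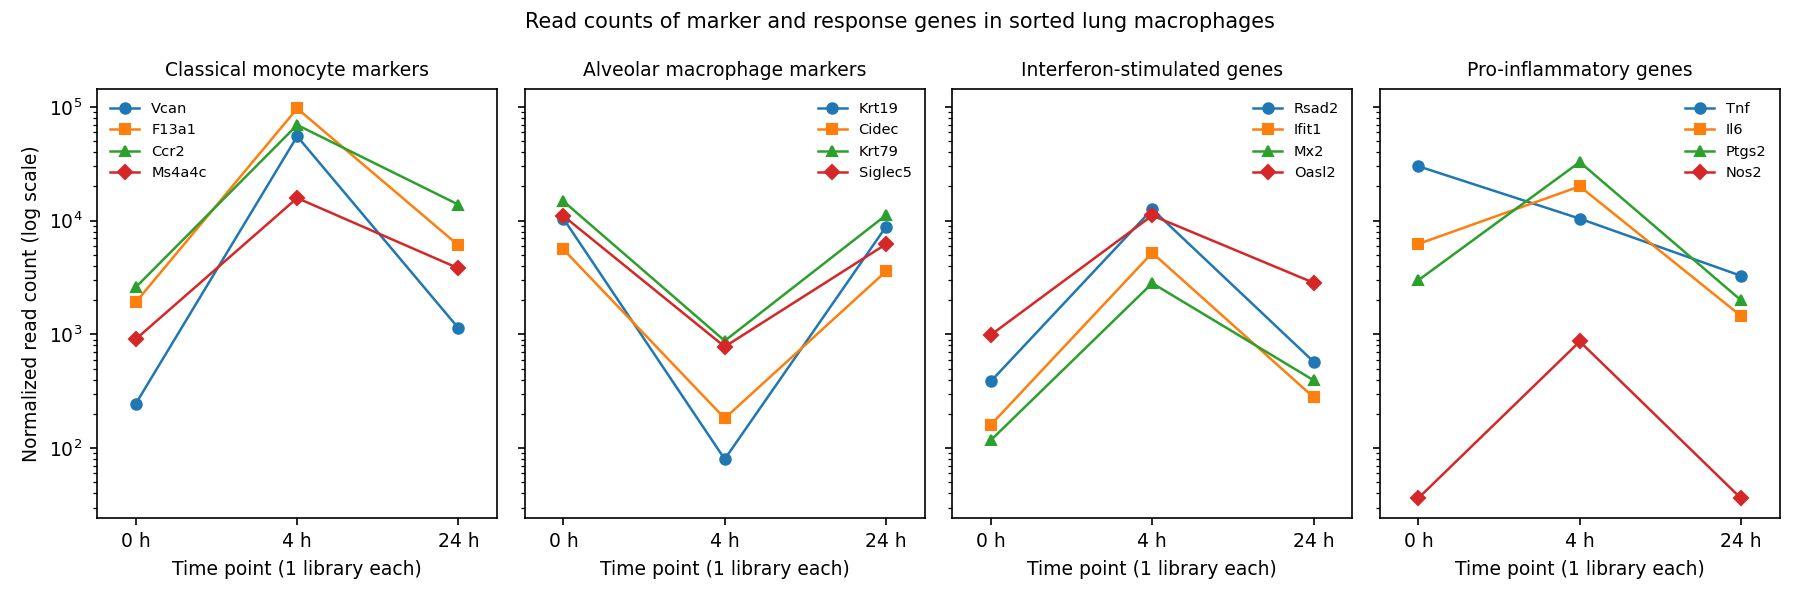
Normalized read counts (log axis) of 16 genes from 4 lists at 0, 4 and 24 h, with 1 library behind each point and lines joining the points of a gene. The 4 classical monocyte genes peak at 4 h, where Vcan reaches 55128, the 4 alveolar macrophage genes are lowest there, where Siglec5 is at 779, and Tnf alone among the 4 pro-inflammatory genes plotted is highest at 0 h, at 30054.

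Of the 13 classical monocyte markers measured, 10 were past the threshold upward at 4 h and 0 downward, with a median deposited log2 fold change of 2.22, and 8 passed when the authors' p-values were adjusted over the list alone. Ccr2, the receptor that draws monocytes out of the bone marrow, was 26.7-fold higher (25.7 to 27.7). Of 25 alveolar macrophage markers, 17 were lower and 1 higher (median -1.30, 5 passing when adjusted over the list alone). The member that was higher was Slc7a2, a transporter of arginine that activated macrophages also make, at 18377 and 81243. Krt79 was 16.9-fold lower (15.6 to 18.2), and Pparg, the nuclear receptor that specifies alveolar macrophages, 4.50-fold lower (4.21 to 4.81). Among the 14 neutrophil markers measured, 12 were higher and 0 lower (median 1.60, 6 adjusted over the list alone), with Lcn2, an iron-binding antibacterial protein, 22.1-fold higher (18.9 to 25.9). S100a9 and S100a8, which make up calprotectin, were 18.0-fold (15.9 to 20.3) and 8.39-fold (7.59 to 9.30) higher and reached 4813 and 3456. The sort excluded Ly6g-positive cells, and Ly6g itself had no value in the tables.

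The interferon-stimulated genes moved as a block, with 34 of 36 higher, 0 lower and a median of 2.09, and 24 passed when adjusted over the list alone. Rsad2, the antiviral enzyme viperin, went from 388 to 12602, 32.5-fold (29.5 to 36.0), and Ifit1, an inhibitor of viral translation, was 32.5-fold higher as well (27.9 to 38.0). Of 24 chemokines, 15 were higher and 3 lower (median 1.46, 2 adjusted over the list alone). Besides Ccl5, Cxcl11, a ligand of CXCR3, was 38.3-fold higher (22.1 to 72.6), while Cx3cl1 was 6.90-fold lower (5.87 to 8.17), Cxcl14 4.80-fold lower (3.37 to 7.02) and Ccl6, an abundant chemokine of alveolar macrophages, 3.64-fold lower (3.60 to 3.69). Of 22 pro-inflammatory cytokines and enzymes, 13 were higher and 2 lower (median 1.34, 2 adjusted over the list alone). Il1f9, an interleukin-36, was 38.3-fold higher (24.0 to 65.1) and Nos2, the inducible nitric oxide synthase, 23.8-fold higher (17.2 to 33.7). The 2 that were lower were Tnf, 2.89-fold (2.82 to 2.96), and Il18, 2.44-fold (2.33 to 2.56). Of 22 NF-kappaB targets and feedback regulators, 6 were higher and 0 lower (median 0.69), or 10 and 0 by plain ratios of at least 2-fold. They were led by Socs3, an inhibitor of cytokine receptor signalling, at 10.1-fold (9.85 to 10.4) and Bcl3, a nuclear I-kappaB protein, at 6.24-fold (5.82 to 6.70).

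Lists of cell cycle, lysosomal, fatty acid and oxidative phosphorylation genes had medians below 0 at 4 h. Of 31 cell cycle genes 26 were lower and 0 higher (median -1.58, 0 adjusted over the list alone), with Cdk1, the mitotic kinase, 9.12-fold lower (7.15 to 11.8) and Birc5, a component of the chromosomal passenger complex, 8.96-fold lower (6.74 to 12.1). Mki67 was the exception in sign, at 2450 and 3270. Of 22 lysosomal genes 5 were lower and 0 higher (median -0.56), including the protease Ctsd at 8.12-fold lower (8.00 to 8.24) and the acid lipase Lipa at 3.95-fold lower (3.84 to 4.07). Of 22 genes of fatty acid uptake, storage and oxidation 4 were lower and 0 higher (median -0.73), among them Etfb, an electron carrier of mitochondrial oxidation, at 2.96-fold lower (2.72 to 3.22). None of 42 nuclear-encoded oxidative phosphorylation genes passed the threshold, but 41 lay below 0 (median -0.35), with the abundant ATP synthase subunit Atp5b at 21189 and 14199. No member of these 3 lists passed when adjusted over the list alone. By plain ratios of at least 2-fold, 8 lysosomal genes were lower and 1 higher, and 9 fatty acid genes were lower and 1 higher. Every list median given in this comparison lay outside the central 95% of 10000 random lists matched on expression.

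Of the 12512 genes, 646 had a deposited p-value below 0.05 where 625.6 would from uniform p-values, and none passed Benjamini-Hochberg adjustment. Plain ratios, which are not shrunken toward 0, put 3634 genes past 2-fold, 1801 higher and 1833 lower.

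At 24 h against 0 h the libraries were closer, with classical monocyte transcripts higher and inflammatory transcripts lower at 24 h than at 0 h. Tnf, the early macrophage cytokine (chromosome 17, 35199366 to 35202007), went from 30054 to 3270 normalized counts, 9.19-fold lower (8.89 to 9.50). Il1a, an interleukin-1, was 7.09-fold lower (6.85 to 7.34). Among monocyte transcripts, Ccr2 (chromosome 9, 124102182 to 124109140) went from 2603 to 13826, 5.31-fold (5.10 to 5.53). By the authors' deposited log2 fold changes, 68 of 12618 genes were at or above 1 and 270 at or below -1, and when the fold changes were recentred on the ribosomal proteins, a shift of -0.41, the split was 4 and 1173.

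Further genes named by the rule were Pyhin1, an interferon-inducible DNA-binding protein, 6.83-fold higher (6.20 to 7.55), Ms4a4c, a membrane protein of monocytes, 4.19-fold higher (3.91 to 4.49), Hpgd, which inactivates prostaglandins, 3.93-fold higher (3.69 to 4.18), Klf2, a transcription factor that restrains myeloid activation, 3.77-fold higher (3.63 to 3.91), and Hp, the hemoglobin-binding protein haptoglobin, 3.56-fold higher (3.40 to 3.73). On the lower side were Rel, a subunit of NF-kappaB, 7.73-fold (7.06 to 8.49), Cbl, a ubiquitin ligase of receptor signalling, 7.63-fold (6.96 to 8.38), and Cxcl1, a neutrophil chemoattractant, 7.09-fold (6.71 to 7.50). Levels of Hpgd at 0, 4 and 24 h were 1172, 1660 and 4602, and those of Klf2 were 3157, 3422 and 11891.

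The deposited folds of the widest differences in this comparison were shrunken furthest, so the threshold missed them. Of 22 genes with a mean of at least 100 normalized counts and a plain ratio of at least 8-fold, 14 fell short of it, and the following were chosen after their values were seen. Il23a, a subunit of interleukin-23, went from 1232 to 5.75, 214-fold lower (104 to 534), against a log2 fold change of -0.17 in the authors' deposited table. The EGF receptor ligands Ereg and Areg were 22.0-fold (19.5 to 24.8) and 9.47-fold (8.71 to 10.3) lower. Nr4a3, an orphan nuclear receptor induced on activation, was 19.9-fold lower (17.0 to 23.4), Hivep3, a zinc finger factor that binds NF-kappaB sites, 35.3-fold lower (29.0 to 43.4), Ppp1r12b 12.7-fold lower (10.1 to 16.1), Hipk2 11.8-fold lower (10.1 to 13.8) and Hr 9.75-fold lower (8.71 to 10.9). The rest were the sex-linked Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, and the hemoglobin gene Beta-s, at 46.7, 1018 and 1664 across the 3 libraries.

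Among 21 pro-inflammatory cytokines and enzymes measured here, 5 were lower at 24 h than at 0 h and 0 higher (median deposited log2 fold change -0.44, and -0.85 after recentring on ribosomal proteins, 3 adjusted over the list alone). Of 22 NF-kappaB targets 5 were lower and 0 higher (median -0.63, recentred -1.04, 0 adjusted over the list alone), with Tnfaip3, the deubiquitinase A20, 5.07-fold lower (4.95 to 5.19). Of 22 chemokines 3 were lower and 1 higher (median -0.31, recentred -0.72, 2 adjusted over the list alone), Cxcl10, an interferon-induced chemokine, being 4.41-fold lower (4.10 to 4.76) and Ccl5 7.49-fold higher (6.33 to 8.92). Of 26 genes of matrix remodelling and growth factors 5 were lower and 0 higher (median -0.37, recentred -0.78, 1 adjusted over the list alone), including Tgm2, a crosslinking transglutaminase, at 3.94-fold lower (3.87 to 4.02). By plain ratios of at least 2-fold the lower members of these lists numbered 10, 9, 5 and 11, and by recentred deposited fold changes 8, 12, 7 and 9. The interferon-stimulated genes stayed on the higher side, with 5 of 36 past the threshold and 0 lower (median 0.57). By plain ratios of at least 2-fold 11 were higher and 1 lower. Recentring on ribosomal proteins gave a median of 0.16 and left 0 higher and 1 lower. This list was led by Rtp4 at 3.78-fold (3.34 to 4.28) and Usp18, which removes ISG15 from its targets, at 3.27-fold (2.81 to 3.83).

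Of 13 classical monocyte markers 9 were higher and 1 lower (median 1.10, 10 adjusted over the list alone), and after recentring 1 was higher and 1 lower with a median of 0.69. Vcan was 4.60-fold higher (4.03 to 5.27), and the member on the lower side was Fn1, encoding fibronectin, 3.44-fold (3.39 to 3.48). Of 14 neutrophil markers 4 were higher and 0 lower (median 0.39, which turned to -0.02 after recentring on ribosomal proteins, with 1 still higher, 2 adjusted over the list alone), with Lcn2 6.20-fold (5.27 to 7.33), S100a9 5.26-fold (4.64 to 5.99) and S100a8 2.53-fold (2.26 to 2.82) higher. Alveolar macrophage markers were on the lower side, with 19 of 25 below 0, a median of -0.41 and -0.82 after recentring, which put 6 past the threshold where 0 of 25 had been, 0 adjusted over the list alone, and the most abundant, Chi3l3, stood at 601110 and 310123. The ribosomal proteins had a median of 0.42 and the oxidative phosphorylation genes 0.32, which turned to -0.09 on recentring, with 0 of 70 and 0 of 42 past the threshold and 0 adjusted over either list alone. Rpl4 stood at 22143 and 27840, and Atp5b at 21189 and 20405. The medians of all lists given for this comparison lay outside the central 95% of random lists.

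No replicate spread stands behind the deposited p-values of these 12618 genes either, so they do not show whether the differences exceed chance. Plain ratios put 562 genes at least 2-fold higher and 1063 at least 2-fold lower, of the 12310 with a level at both times.

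At 24 h against 4 h much of the 4 h difference was reversed, with inflammatory, interferon and monocyte transcripts lower and alveolar macrophage and cell cycle transcripts higher. Irg1 (Acod1), the enzyme that makes itaconate (chromosome 14, 103047011 to 103056573), went from 13212 to 247, 53.6-fold lower (47.8 to 60.3), and Vcan was 48.6-fold lower (46.1 to 51.3). Cxcl10 was 33.7-fold lower (31.5 to 36.1). Krt19 was 111-fold higher (86.3 to 144), at 8841, and Ltc4s, which makes leukotriene C4, 14.9-fold higher (12.8 to 17.5). By the authors' deposited log2 fold changes, 913 of 12578 genes were at or above 1 and 1278 at or below -1, and with recentring on the ribosomal proteins, a shift of -0.37, these counts were 378 and 2442.

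The other genes named by the rule were X99384 (23.0-fold higher, 19.5 to 27.3), Cidec (19.6-fold higher, 16.6 to 23.3), Cd2 (18.5-fold higher, 16.0 to 21.6) and Krt79 (12.7-fold higher, 11.8 to 13.8). Lower at 24 h were Hivep3, 41.2-fold (33.8 to 50.7), Tarm1, 32.6-fold (27.4 to 39.1), and Scgb1a1, 37.8-fold (31.7 to 45.5). Scgb1a1 encodes the secretoglobin of club cells in the airway epithelium, and its levels of 90.6, 3977 and 105 marked out the 4 h library.

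Of 22 pro-inflammatory cytokines and enzymes, 18 were lower at 24 h and 0 higher (median deposited log2 fold change -1.80, 9 adjusted over the list alone). Csf3, the granulocyte growth factor G-CSF, was 131-fold lower (55.8 to 406) and Il23a 94.2-fold lower (45.3 to 236). Chemokines were lower in 18 of 24 and higher in 3, or 20 and 0 after recentring (median -1.75, 5 adjusted over the list alone), Cxcl11 by 23.6-fold (15.6 to 37.2) on the lower side and Ccl6 by 3.05-fold (3.01 to 3.09) and Cxcl14 by 3.24-fold (2.25 to 4.77) on the higher side. Interferon-stimulated genes were lower in 28 of 36 and higher in 0 (median -1.52, 6 adjusted over the list alone), with Ifi205 22.1-fold (19.9 to 24.6) and Rsad2 21.9-fold (20.3 to 23.7) lower. NF-kappaB targets were lower in 18 of 22 and higher in 0 (median -1.49, 0 adjusted over the list alone), with Rel 14.3-fold (13.1 to 15.7) and Socs3 12.1-fold (11.8 to 12.4) lower. Matrix remodelling genes were lower in 9 of 26 and higher in 1 (median -0.79, 4 adjusted over the list alone). After recentring on ribosomal proteins 14 of these 26 were lower and 0 higher (median -1.15). Mmp13, a collagenase, was 61.8-fold lower (46.8 to 83.3) and Hbegf, a growth factor for epithelium, 22.1-fold lower (16.8 to 29.5).

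Alveolar macrophage markers were higher in 13 of 25 and lower in 1, Slc7a2 (median 1.39, 4 adjusted over the list alone), with the same counts after recentring. Classical monocyte markers were lower in 9 of 13 and higher in 0 (median -1.47, 3 adjusted over the list alone), including F13a1 at 16.0-fold lower (15.6 to 16.4). Neutrophil markers were lower in 9 of 15 and higher in 0 (median -1.26, 0 adjusted over the list alone), with Mmp8, a collagenase of granules, 16.1-fold (15.1 to 17.1) and Hdc, which makes histamine, 9.81-fold (8.60 to 11.2) lower. By plain ratios of at least 2-fold, 10 neutrophil markers were lower and 3 higher. S100a8 and S100a9 were 3.32-fold (3.11 to 3.55) and 3.41-fold (3.22 to 3.61) lower. Cell cycle genes were higher in 23 of 31 and lower in 0 (median 1.33, 0 adjusted over the list alone), or in 15 and 1 after recentring (median 0.96), with Cdk1 7.40-fold (5.80 to 9.57) and the replication helicase subunit Mcm7 6.81-fold (5.68 to 8.22) higher. Oxidative phosphorylation genes had a median of 0.62, or 0.25 after recentring on ribosomal proteins, with 2 of 42 past the threshold and 0 after recentring, Cox5a at 2.57-fold higher (2.44 to 2.71) and Ndufs7 at 2.48-fold higher (2.25 to 2.73), and 0 adjusted over the list alone. By plain ratios of at least 2-fold 11 of the 42 oxidative phosphorylation genes were higher and 0 lower. The medians given for this comparison lay outside the central 95% of random lists.

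**Figure D2:**
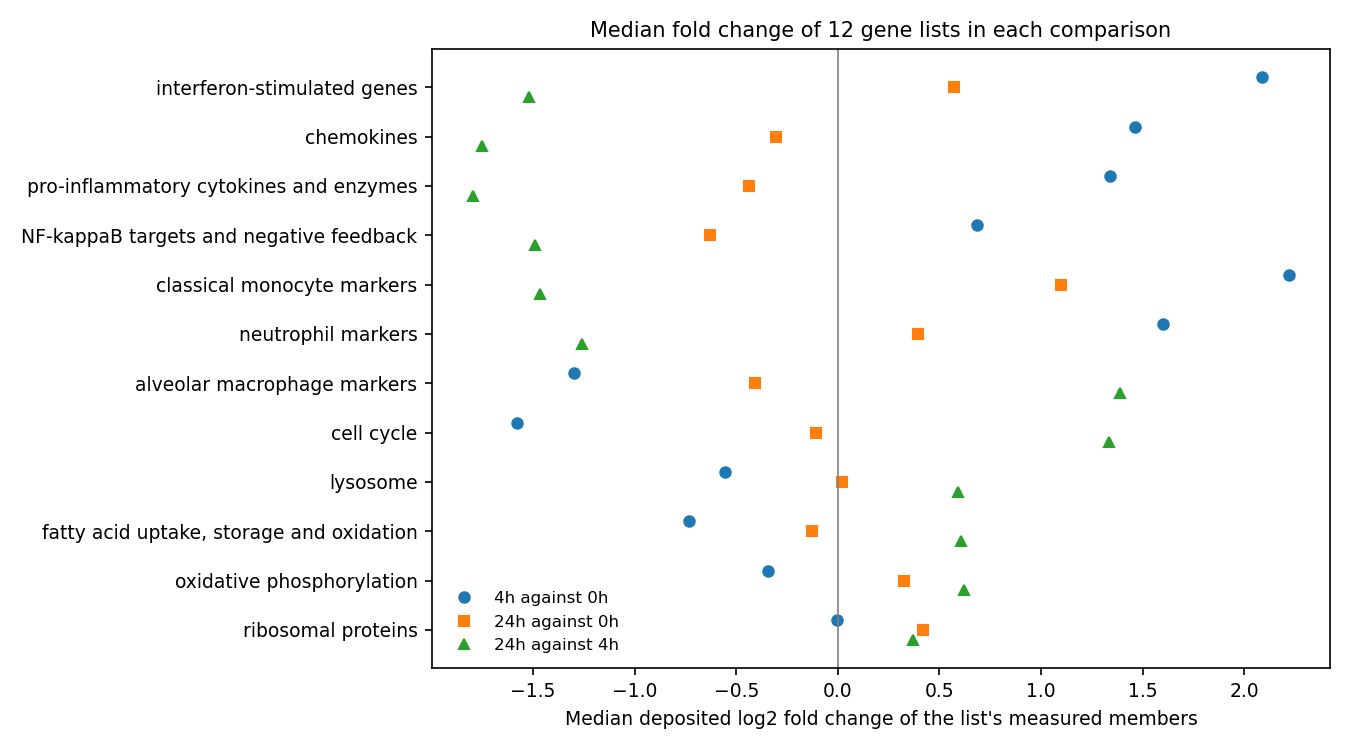
Median deposited log2 fold change (horizontal axis) of the measured members of 12 gene lists (rows) in the 3 comparisons (symbols), from 1 library per time point. Interferon-stimulated genes move from 2.09 at 4 h against 0 h to -1.52 at 24 h against 4 h and alveolar macrophage markers from -1.30 to 1.39, and the 24 h against 0 h medians of oxidative phosphorylation (0.32), neutrophil markers (0.39) and lysosomal genes (0.02) turn below 0 when recentred on ribosomal proteins.

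Genes that differed at 4 h were often past the threshold in the opposite direction at 24 h. Of 1109 genes higher at 4 h, 689 (62.1%) were lower at 24 h against 4 h, where independent lists would share 114.4. Of 1101 genes lower at 4 h and listed in both tables, 682 (61.9%) were higher at 24 h, where independent lists would share 80.4. With recentring on ribosomal proteins only 378 genes in all were higher at 24 h against 4 h, so fewer than 682 could return on that scale. These overlaps were not recounted with recentring. Both comparisons use the 4 h library, which by itself sets chance values against each other. In plain ratios 1253 genes were at least 2-fold higher at 4 h and then at least 2-fold lower, against 387.4 in simulated libraries with no effect, and 1212 the reverse, against 383.4. The covariance of the log2 ratios across genes was -1.19, against -0.30 in the simulation, which leaves -0.89 beyond it. The simulation gave every library the same spread, an SD of 0.54 on the log2 scale, set from the 24 h against 0 h ratios. A 4 h library with more error of its own than the others would also exceed the simulated values. The excess alone therefore does not show that expression returned, and no replicate of the 4 h library was there to measure its error.

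The deposited p-values of 24 h against 4 h have the same limit, with no replicate spread behind them. Plain ratios put 1851 genes at least 2-fold higher and 2121 at least 2-fold lower.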

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

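The counts of genes past a threshold depended on how a fold change was defined more than on filters. No paired analysis was possible because each time point had 1 library, which also left no replicate to omit. An adjusted p threshold of 0.01 gave 0 genes in each comparison, as did the size threshold together with an adjusted p, and 0.05, the last chosen after seeing the data. Plain ratios with a pseudocount of 1 gave 3634 genes at 4 h against 0 h, 1625 at 24 h against 0 h and 3972 at 24 h against 4 h, in place of 2237, 338 and 2191, since deposited folds are shrunken, and with a pseudocount of 5 they gave 3440, 1474 and 3772. Recentring on ribosomal proteins gave 1177 genes at 24 h against 0 h, because it shifts each fold change by -0.41. Among settings chosen after seeing the data, the authors' unadjusted p below 0.05 gave 646 genes at 4 h against 0 h and 558 at 24 h against 4 h, and a plain ratio of at least 8-fold with a mean of at least 100 gave 267, 22 and 199, a stricter criterion by construction. The other gene counts were within 1.5 times, including those with a mean of at least 100 (1621, 300 and 1664), without chromosomes X and Y (2165, 328 and 2119) and with length and GC trends removed (1878, 244 and 1783).

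The number of lists outside the central range was 19, 16 and 18 in the 3 comparisons and 15 to 20 under the alternatives. Of 115 list results, 106 stayed inside or outside the central range with unmatched random lists, 112 without shared members and 113 with plain ratios. Those that stayed outside kept their sign, which was not checked for those inside. All 115 did so with a mean of at least 10, but that filter removes few or no genes already limited to a pair mean above 10. Recentring on ribosomal proteins, also added later, turned 5 medians, among 112 list results, that had lain outside the central range: at 24 h against 0 h oxidative phosphorylation to -0.0871, interstitial macrophage markers to -0.15, neutrophil markers to -0.0184 and fibroblast and mural cell markers to -0.0268, and at 24 h against 4 h the tricarboxylic acid cycle list to -0.13. The cause is the constant shift itself, and whether ribosomal transcripts or the rest moved was not tested. With length and GC trends removed, the ribosomal median went from 0.42 to 0.33 at 24 h against 0 h. At 24 h against 4 h it went from 0.37 to 0.18, so part of the shift goes with those trends. Gapdh, which like ribosomal proteins has many processed pseudogenes, had only 131, 110 and 151 reads at 0, 4 and 24 h, so reads shared with pseudogenes may have been dropped and the ribosomal anchor may rest on those left.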

Other observations

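All tests of explanations reported here were chosen after the data and the patterns were seen, and for sex, the share of alveolar macrophages, neutrophils and tissue digestion the values they rest on had been seen too, whereas for chromosomes X and Y and for length and GC content what each outcome would mean was written before the test was run. Genes of lipid mediator synthesis and their receptors, not described above, went both ways at 4 h against 0 h, with 5 of 16 higher and 3 lower by deposited log2 fold change. Ptgs2, the inducible cyclooxygenase, was 10.9-fold higher (10.5 to 11.3) and Ptges, which makes prostaglandin E2, went from 441 to 2720, while Alox5, which starts leukotriene synthesis, was 20.6-fold lower (18.5 to 23.1) and Ltc4s 12.9-fold lower (11.1 to 15.2). At 24 h against 4 h, 3 of the 16 were higher and 3 lower, with Alox5 9.97-fold higher (8.91 to 11.2) and Ptgs2 16.4-fold lower (15.8 to 17.1). Among 25 genes of efferocytosis, the clearing of apoptotic cells, 3 were higher and 6 lower at 4 h against 0 h (median -0.35). Msr1, a scavenger receptor, was 16.2-fold higher (15.3 to 17.1) and Thbs1, a bridging molecule, 5.31-fold higher (5.22 to 5.40), while Mertk was 6.31-fold lower (5.96 to 6.68) and Abcg1, a cholesterol exporter, 6.62-fold lower (6.43 to 6.82).

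Of 12 genes of iron handling 5 were higher and 0 lower at 4 h against 0 h (median 0.77, and 0.47 with length and GC trends removed), Lcn2 among them. Hamp, which encodes hepcidin, had 1 read at 0 h, 460 at 4 h and 4 at 24 h, a ratio of 625 between 4 h and 0 h with a counting interval of 112 to 24750. Of 18 glycolysis genes 2 were higher and 1 lower, with Slc2a1, the glucose transporter GLUT1, 3.85-fold higher (3.62 to 4.10) and Hif1a 3.79-fold higher (3.63 to 3.95), and Aldoa the member on the lower side. Transcripts of cells outside the gate were present too. Scgb1a1 of club cells was 43.9-fold higher at 4 h than at 0 h (35.9 to 54.3), and the hemoglobin gene Beta-s 21.8-fold higher (16.4 to 29.6). Of 18 lung epithelial markers 6 were higher, Scgb3a2 among them, and 2 lower, Epcam and Cdh1. Dendritic cell markers were higher in 6 of 11 and lower in 2 (median 1.05), while the median of non-classical monocyte markers was -0.30. Of 14 T and NK cell markers listed only 7 had a value, with 5 higher and 1 lower (median 1.23). A value needs a pair mean above 10, so scarce members count only where a library of the pair held enough reads. The gates on GFP and CD64 should remove T and NK cells, and the source of these transcripts was not tested. At 24 h against 0 h dendritic cell markers were higher in 3 of 11 and lower in 0 (median 0.58, or 0.17 after recentring on ribosomal proteins). Medians were also above 0 for T and NK cell markers (0.43 over the 5 of 14 with a value, recentred 0.02) and endothelial markers (0.41, recentred 0.00). The same held for fibroblast and mural cell markers (0.38), which turned to -0.03 on recentring.

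Sex-linked transcripts differed between the 0 h library and both later ones. The lowest of 10 folds, of Xist and 4 Y-linked genes between the 0 h library and each later one, was 208, for Uty at 24 h (57.3 to 1723). This fits female mice behind the 0 h library and male mice behind the others, a difference that no label gives, so sex may be confounded with time in both comparisons with 0 h. Genes on chromosomes X and Y made up only 2.96% of the genes past the threshold at 24 h against 0 h, against 3.11% of all genes tested. By plain ratios of at least 2-fold they made up 3.20% of 1625 genes, with 4 on Y where the deposited threshold had 0. Genes on these chromosomes are too few to make up either count, and for the plain ratios their small share of all genes set that in advance. The shares do not measure how far sex contributed. Effects of sex on other chromosomes cannot be separated from time in this design.

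Inflammatory transcripts were lower at 24 h than at 0 h, and the 2 lists together had a median of -0.57. Taking off the median of genes of like length and GC content left -0.58, below all random lists, which argues against those trends. A lower share of alveolar macrophages and lower expression within them cannot be told apart, since the median log2 ratio of alveolar markers (-0.55) lay only 0.32 above that of all 43 members (-0.87) and no count of cells by type was available. More activation of the 0 h cells during digestion was not seen in the 17 immediate early genes, with a median of 0.0511, 9 higher and 8 lower. Recentring on ribosomal proteins gave a median of -0.36, so without replicates this explanation stays open. A biological candidate explanation, damped NF-kappaB output after LPS, was not tested apart from these, and it also depends on whether the 0 h mice had inhaled LPS, which is not stated; replicate libraries with untreated mice and counts of cells by type would be the test.

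At 4 h alveolar macrophage markers were lower and classical monocyte markers higher. Length and GC content do not account for it, since both medians kept their sign and size when those trends were taken off. The alveolar median was -1.30 over 25 markers before and -1.46 after, over the 22 with a length and GC content. The monocyte median went from 2.22 to 2.30 over the same 13 markers. The Ly6g gate should exclude neutrophils, but the counts leave a part from them open. Counts of a bulk library do not give the cell type that S100a8 and S100a9 reads came from. Per kilobase the higher of S100a8 and S100a9 was 43.8% of the lowest of Vcan, F13a1 and Ccr2 with median transcript lengths and 209% with the longest. The 209% is set by Vcan. With the longest transcripts S100a9, at 9274 per kilobase, lay above Vcan (4436) but below Ccr2 (12115) and F13a1 (24509). A lower share of alveolar macrophages among the sorted cells and lower expression within them cannot be told apart, as the 0 h over 4 h ratios of 25 markers ranged 19.6-fold between the 10th and 90th percentiles, from 0.813 to 16.0, and no reference of monocyte expression was used here. Entry of monocyte-derived cells that express CD64 may therefore stand beside a change of state in resident cells as a hypothesis, which lineage tracing or sequencing of single cells would test.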
